A study of Lactiplantibacillus plantarum with 8 samples.

How the data were processed

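RNA of Lactiplantibacillus plantarum was compared between the wild type and a strain that the labels name as a sortase A deletion mutant, on 8 arrays with 2 dyes each. Per the labels, both strains were grown in pH-controlled fermentors at 37 °C with 1.5% glucose and sampled in logarithmic growth (optical density 1) or in late stationary phase. Each phase had 4 arrays: mutant in Cy5 against wild type in Cy3, the same pair with the dyes exchanged, mutant against mutant, and wild type against wild type. The labels do not say which cultures the arrays share, so p-values measure only the spread between arrays, which may be technical.

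The deposited scanner tables give the mean signal intensity and mean local background intensity of each spot in each dye, uncorrected and not normalized per the file headers, with a spot flag code per dye. The image software and the meaning of the codes are not given in the sources used here. The authors also deposited a table with a ratio per spot and array, whose scale and direction were found by setting it against the scanner values. Its rows, taken in the order of the scanner tables, correlated at 0.924 to 0.993 with Cy3 over Cy5 after background subtraction, and a value was missing exactly where a background-subtracted signal was 0 or less. The ratio columns had medians between 0.967 and 1.02, so the values were centred ratios of Cy3 over Cy5, with the normalization method unknown. All ratios below are the other way round, Cy5 over Cy3.

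Each array held 9271 spots, of which 9170 were probes for 3092 locus tags, 60 were control spots and 41 others named no gene. Of the locus tags, 3022 had 3 probes or more, 34 had 2 and 36 had 1. The files do not pair locus tags with gene names, and 0 of the 3092 tags were found in the gene table given as reference. Gene lists defined by symbol or product, sortase substrates among them, were therefore void and are not analysed here. Lists defined by locus tag ranges before the data were examined were used, namely the neighbours of lp_0514, the plantaricin locus, the capsular polysaccharide span from lp_1176 to lp_1238, teichoic acid genes, the F-type ATP synthase, fatty acid synthesis and the prophages. What each range encodes, and lp_0514 as the sortase A gene, were taken from general knowledge of this genome. The rule for named genes, also fixed in advance, would have named lp_0514, its neighbours, up to 10 passing genes per direction and list members, but only 2 locus tags per direction are printed besides lp_0514, because the tags have no names here.

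Background was corrected with normexp (offset 50) and log2 ratios were normalized within each array by loess (span 0.3) in limma 3.58.1 under R 4.3.3, with control spots at weight 0 and left out of the tests. Probes of a gene were averaged, and genes with a value on all arrays of a fit were tested. The plan was to leave out spots marked by the scanner software. Code 2 covered 69810 channel values with a median signal of 1.41 times background, code 3 covered 33165 with 6.8 times, and unmarked spots lay at 6.11 times. Leaving out code 3 alone was decided after the files were seen, and it removes many bright spots, so the alternatives with code 3 kept and with codes 2 and 3 both left out are given in the closing section. The plan named 1 fit per phase with the strain effect (1, -1, or 0 for the same-strain arrays) and a gene-specific dye term, lmFit and eBayes, and a Benjamini-Hochberg adjusted p threshold of 0.05. The difference between phases was fitted on all 8 arrays, lists with at least 3 measured members were tested with camera (preset correlation 0.01), and a same-strain contrast was fitted as background.

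The fits were tested on simulated arrays with 200 changed genes and the spread of each real array. Of the changed genes tested in the logarithmic fit of 2121 genes, 66.7% of 72 were recovered at 2-fold and 100% of 68 at 4-fold, with 4 unchanged genes called. In the stationary fit of 2072 genes the shares were 88.5% of 61 and 100% of 69, with 7 unchanged genes called. In the fit of the difference between phases, over 1858 genes, they were 47.4% of 57 and 98.4% of 62, with 1 unchanged gene called. With no change simulated, the fits called 1, 0 and 0 genes. A list of 40 genes shifted by 0.5 on the log2 scale was called in both phases, and no unshifted list was. The simulated errors were independent between probes, which real errors need not be. Each simulated change was also present in full on every array and in the direction of its label. Both the labels and the second array of each slide are in doubt below, so these shares need not hold for the real arrays.

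Alternatives covered the background correction, the normalization, dim probes, marked spots, the probe summary, the dye term, the arrays in the fit, the slide as a block, the authors' ratios and each array left out in turn. Fits on the first or the second array of each slide alone were added after the data were seen. The number of arrays limits the precision.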

Results

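Transcript levels were measured on 8 arrays with 2 dyes, 4 per growth phase, to find genes whose expression differs when Lactiplantibacillus plantarum lacks sortase A, the enzyme that links surface proteins to the cell wall. Each phase had 2 arrays of mutant against wild type with the dyes exchanged, 1 array of mutant against mutant and 1 of wild type against wild type. The arrays lay in pairs on 4 slides, and slides 1 and 2 carried the logarithmic labels. Both arrays of a slide carried the same 3092 locus tags.

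The targeted gene did not follow the strain labels. lp_0514, taken as the sortase A gene, gave clear signal in some channels labelled mutant and lay near background in some channels labelled wild type. On the logarithmic array labelled mutant in Cy5 and wild type in Cy3, its median signal over 3 probes was 9.17 times background in the channel labelled mutant and 1.46 times in the channel labelled wild type. On the logarithmic array labelled wild type in both dyes it was 1.18 times background in Cy5 and 1.3 times in Cy3. On the first stationary array of mutant against wild type it was 8.9 times background in the channel labelled mutant and 14.7 times in the channel labelled wild type. On the stationary array labelled mutant in both dyes it was 12.1 times background in Cy3 and 1.46 times in Cy5.

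With more than 3 times background counted as present, a limit set after the values were seen, 2 of the 8 channels on the first array of each slide matched their strain label. Exchanging the dyes gave 4 of 8, and other layouts of the labels are given in the closing section. On the second array of each slide the probes disagreed. The first probe lay between 3.62 and 13.9 times background in all 8 channels, whereas the median over the probes lay between 1.32 and 3.44 times. Whether the probes lie inside the deleted part is not given in the sources used here. Strains are therefore named below by what the channel was labelled, and no direction below is settled as an effect of the deletion.

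**Figure D1:**
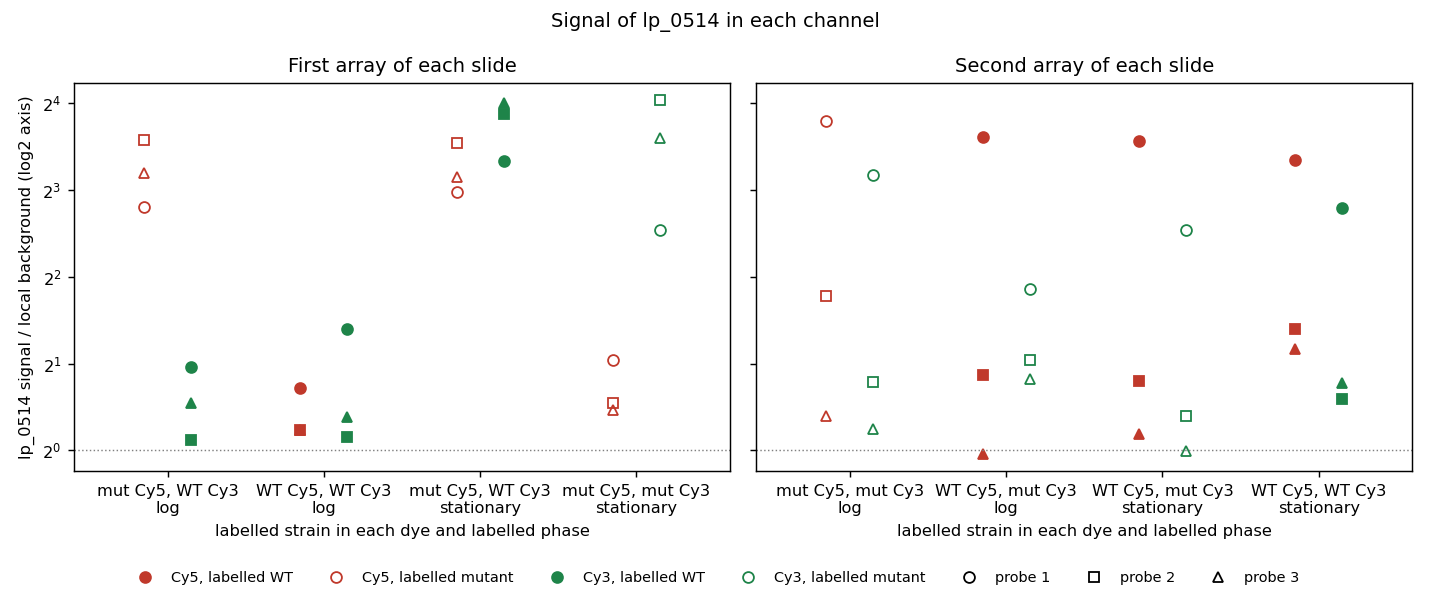
Signal of lp_0514 over local background (log2 axis) for each of 3 probes in the Cy5 and Cy3 channel of the 8 arrays, with filled symbols for channels labelled wild type and open symbols for channels labelled mutant. On the first array of each slide the gene lies far above background in 4 channels and near it in 4, without following the labels.

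The first and the second array of a slide also differed in the profile over all genes. Channels of first arrays correlated across gene probes at 0.971 on average within a labelled phase and at 0.967 between phases. Channels of second arrays correlated at 0.842 and 0.849, and channels of different positions only at 0.418 within a phase and 0.417 between phases. Median signal was 4.65 to 6.74 times background on first arrays and 1.45 to 1.97 times on second arrays. Between 2 probes of the same gene, levels correlated across 3056 genes at 0.883 to 0.91 on first arrays and at 0.398 to 0.508 on second arrays. Genes are not independent replicates in these correlations. Within and between labelled phases the correlations hardly differed, so phases too are named below only as labelled. In each phase the array labelled mutant in Cy5 and wild type in Cy3 was a first array, and the array with the dyes exchanged was a second array. A bias of the ratios that differs between positions therefore enters every fitted strain effect below, and no position term was fitted.

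**Figure D2:**
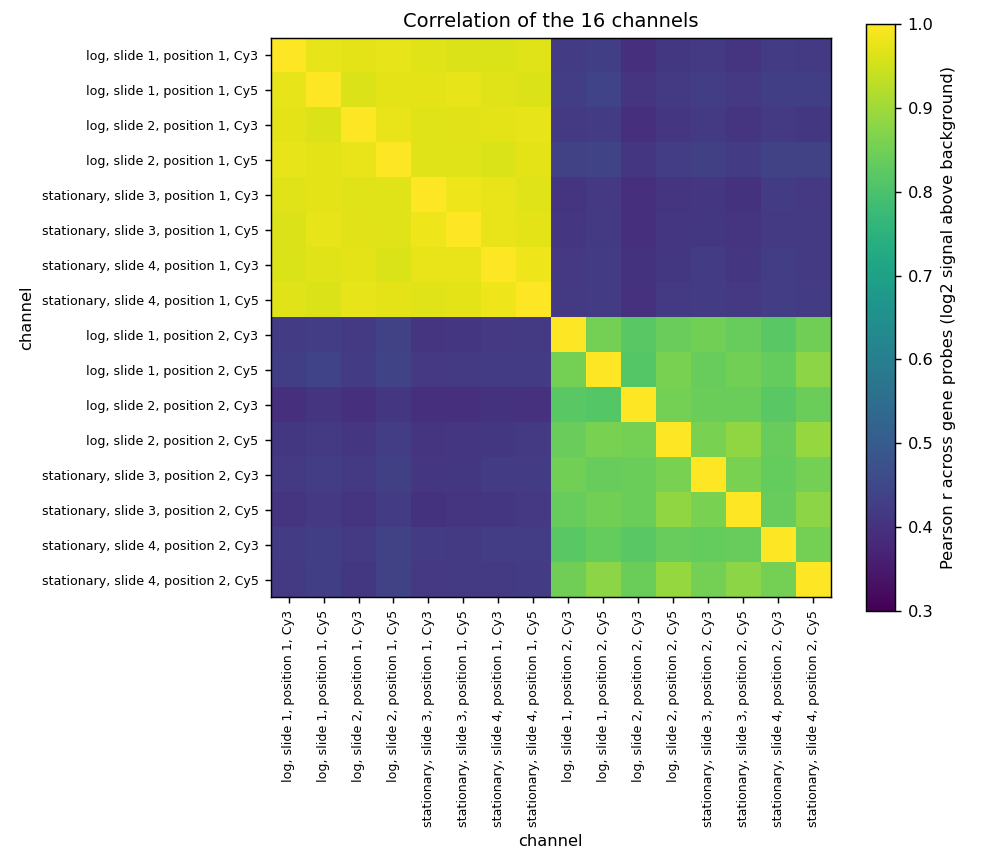
Pearson correlation across gene probes of log2 signal above background between all 16 channels, ordered by position on the slide, slide and dye. Channels of first arrays correlate at 0.961 or more between different arrays, channels of different positions at 0.443 or less.

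In logarithmic phase, genes of the capsular polysaccharide span, whose products build the polysaccharide coat of the cell, stood out between the channels labelled mutant and wild type. Of 2121 genes tested, 12 passed the threshold, 5 higher and 7 lower in the channel labelled mutant, and 7 of the 12 lay in the capsular span. With the direction turned, the split would be 7 higher and 5 lower. With median centring in place of loess it was 4 higher and 3 lower, all 7 among the 12. lp_0514 itself was higher in the channel labelled mutant, against the deletion, with a fitted log2 difference of 3.17 (SE 0.36, 4 arrays, adjusted p = 0.000949 in limma). Its size is not exact, because at least 1 channel of both arrays of mutant against wild type lay near background, and it was 2.12 with no background correction, which no longer passed. In the fitted span, lp_1198 was at -2.68 (SE 0.41, adjusted p = 0.0064) and lp_1197 at -2.56 (SE 0.41, adjusted p = 0.00828), while their neighbour lp_1196 was at 1.97 (SE 0.28, adjusted p = 0.0039). Without the logarithmic array labelled mutant in Cy5 and wild type in Cy3 these were at -0.98, -0.89 and 1.37 and did not pass. lp_1198 also did not pass with the median of probes, lp_1197 with median centring and lp_1196 with dim probes left out, and the other settings that ended these calls are given in the closing section.

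Outside the span, lp_0076 was higher in the channel labelled mutant at 2.38 (SE 0.36, adjusted p = 0.00559). It was at 1.42 without the logarithmic array labelled mutant in Cy5 and wild type in Cy3, and at 3.34 without the one with the dyes exchanged. In limma it did not pass with no dye term (adjusted p = 0.168) or with code 3 spots kept (adjusted p = 0.0622). The fit that chose the 12 genes used both arrays of mutant against wild type, so a shared direction on them is in part fixed by the selection. With the dyes taken into account, all 12 genes had the same direction on both arrays of mutant against wild type, but the sizes differed between them, down to 0.13 on the array with the dyes exchanged. With no background correction 11 of 12 did, and with plain subtraction or the authors' ratios 10 of the 11 with both values. For lp_0514 log2 Cy5 over Cy3 was 4.48 on the array with the channel labelled mutant in Cy5 and -1.87 on the array with the dyes exchanged, and for lp_1198 it was -4.81 and 0.55. The -1.87 rested on 2 spots near background, at 2.06 and 1.77 times it in the channel labelled mutant and 1.83 and 0.973 times in the channel labelled wild type. The first probe, left out for its code 3, went the other way, at 3.62 times in the channel labelled mutant and 12.2 times in the channel labelled wild type. The value was -0.90 with code 3 spots kept, -0.57 with no background correction, -0.11 with both and -0.00856 in the authors' ratios, so the array with the dyes exchanged gave little support for the direction of lp_0514. Without the first of these arrays 0 genes passed, without the second 4 did, and without the array labelled mutant in both dyes 21 did. With the slide as a block 9 genes passed, 7 of them among the 12, and lp_0076 no longer did (1.76, adjusted p = 0.0727). In fits with that block the strain effect comes only from differences between the first and the second array of a slide. It therefore cannot be told apart from position. With code 3 spots kept 4 genes passed, all of them among the 12, and with no background correction, plain subtraction, a test per probe or the authors' ratios 0 did.

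**Figure D3:**
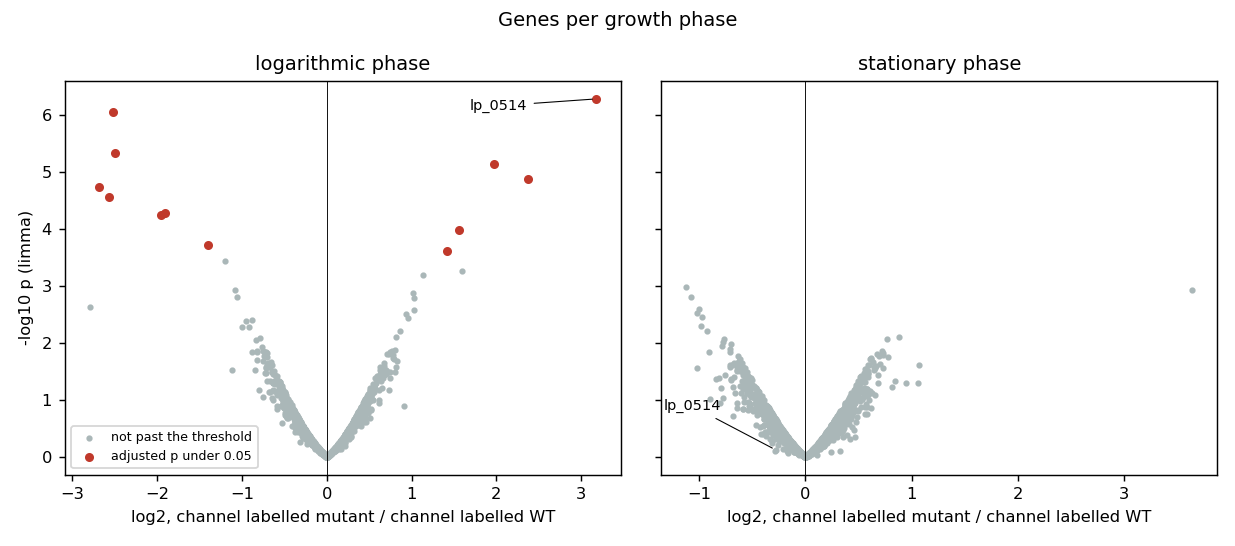
Log2 ratio of the channel labelled mutant over the channel labelled wild type (x axis) against -log10 of the limma p (y axis) for each gene tested in logarithmic (2121 genes) and stationary phase (2072 genes). Red points are the 12 genes past the adjusted threshold, all in logarithmic phase, with lp_0514 on the side of the channel labelled mutant.

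The capsular change sat in a run of 11 consecutive genes starting at lp_1197, a run chosen after its values were seen. With all spots kept, its median log2 Cy5 over Cy3 was -3.61 on the logarithmic array labelled mutant against wild type, a 12.2-fold lower signal in the channel labelled mutant, with genes between -5.03 and -1.72. The stationary array labelled mutant in both dyes showed the same run at 3.79, or 13.8-fold, with genes between 2.21 and 5.06. The logarithmic array labelled wild type in both dyes was at -0.35 and the first stationary array of mutant against wild type at -0.01. On the 4 second arrays the run had medians between -0.44 and 0.56. lp_1196, next to the run, went the other way, at 2.48 on the first of these arrays and -2.39 on the stationary array labelled mutant in both dyes. Of the 47 other genes of the span, 0 lay beyond 1 in either direction on the logarithmic array of mutant against wild type and 1 on the stationary array labelled mutant in both dyes.

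**Figure D4:**
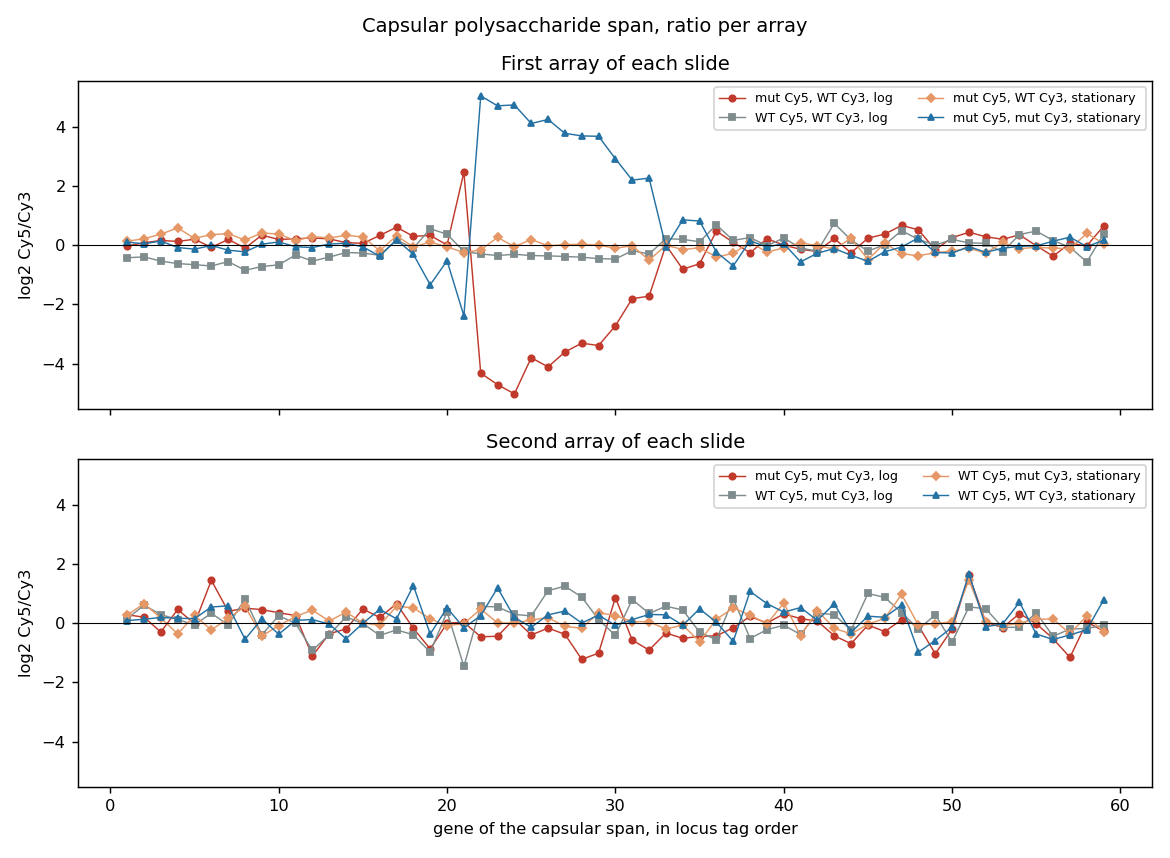
Log2 Cy5 over Cy3 of the 59 genes of the capsular span in locus tag order, for the first (top) and second (bottom) array of each slide, with 1 line per array. The run of 11 genes has medians of -3.61 and 3.79 on 2 first arrays and lies near 0 on the other 2.

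As a list, the capsular span had 44 measured members in logarithmic phase, 1 higher and 6 lower in the channel labelled mutant, with 10 passing when adjusted over the list alone. Camera gave an adjusted p of 0.00362 towards lower values (median -0.05, mean -0.38). The camera adjusted p was 0.233 with an estimated correlation. That correlation was -0.00797, below the preset 0.01, so a higher correlation between members is not what raised the p. For the simulated shifted list the camera adjusted p also rose in this setting but still passed. It went from 1.38e-19 to 0.0363 in logarithmic and from 1.31e-19 to 0.0357 in stationary phase. The plantaricin locus, which encodes bacteriocin production, had 0 of 23 members past the threshold (median -0.03, camera adjusted p = 0.568), and the prophages had 0 of 119 (median 0.01, adjusted p = 0.568). The neighbours of lp_0514 had 0 of 3 measured members past the threshold (median -0.06, adjusted p = 0.53). With all spots kept, the 10 neighbours had medians between -0.04 and 0.06 on the 4 first arrays, beside ratios of 3.93 and -3.74 for lp_0514 on 2 of them. The teichoic acid, ATP synthase and fatty acid lists had fewer than 3 measured members and were not tested.

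In stationary phase no gene passed the threshold between the channels labelled mutant and wild type in the planned fit. Of 2072 genes, 0 passed the threshold in limma, with 112 at an unadjusted p under 0.05 and a smallest adjusted p of 0.88. lp_0514 was at -0.28 (SE 0.85, 4 arrays, adjusted p = 0.98), with log2 Cy5 over Cy3 of 0.14 on the array with the channel labelled mutant in Cy5 and 0.70 on the array with the dyes exchanged. In the channels labelled mutant and wild type its median signal was 8.9 and 14.7 times background on the former array. On the latter it was 1.32 and 1.74 times. Neither array clearly separated its channels by the deleted gene, so the 0 cannot be read as absence of an effect of the deletion. The plantaricin locus lay lower in the channel labelled mutant as a list, with a median of -0.20 over 24 measured members and a camera adjusted p of 0.0126. That adjusted p was 0.405 with an estimated correlation, 0 members passed among all genes and 1 passed when adjusted over the list alone. The capsular span had 0 of 40 members past the threshold (median -0.08, adjusted p = 0.374) and the prophages 0 of 120 (median 0.05, adjusted p = 0.192), with 0 in either when adjusted over the list alone. Without the array labelled wild type in both dyes 13 genes passed. lp_2778 (3.64, SE 0.74, adjusted p = 0.88) passed with the slide as a block (3.64, adjusted p = 3.29e-06), with the same-strain arrays left out (adjusted p = 0.00204) and without the first array of mutant against wild type (adjusted p = 1.38e-05), but its value rested on 1 spot whose Cy5 background of 28630 exceeded its signal of 23930, and it was 0.08 with no background correction.

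The difference between the labelled phases was tested directly on all 8 arrays. With the labels in doubt, its result cannot be read as one about growth phases. Of 1858 genes, 0 passed in limma, with 94 at an unadjusted p under 0.05 and a smallest adjusted p of 0.903, so no difference between phases was shown for the 10 of the 12 genes of logarithmic phase that were in this fit. With the slide as a block, or without the first stationary array of mutant against wild type, 1 gene passed, again lp_2778. Without the stationary array labelled mutant in both dyes 1 gene passed, lp_0514 (stationary minus logarithmic -3.45, adjusted p = 0.0216).

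The arrays labelled with the same strain in both dyes were planned as background. The stationary array labelled mutant in both dyes differed between its dyes in lp_0514. Its contrast is therefore not a background of the method alone. That array also enters the dye term of fits on first arrays alone, where the channel labelled mutant was always in Cy5. On the first arrays labelled wild type and mutant in both dyes, log2 Cy5 over Cy3 of lp_0514 was -0.18 and -3.46. The values of lp_0514 in these fits, 6.30 in logarithmic and 1.96 in stationary phase, therefore cannot be read as strain effects. This also holds for the stationary fits that leave out 1 array of mutant against wild type (-2.33 and 1.77). A contrast between the mutant array and the wild type array of a phase called 0 of 2121 genes in logarithmic phase (94 at an unadjusted p under 0.05) and 0 of 2072 in stationary phase (109). With the strain effect fitted as well, it called 1 and 0 genes. Among first arrays, 22 of 3092 genes lay beyond 1 on the log2 scale on the logarithmic array of mutant against wild type and 7 on the stationary one, against 14 on the logarithmic array labelled wild type and 21 on the stationary array labelled mutant in both dyes.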

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

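Except for the tests of a turned grid, of weak signal and of probe agreement on second arrays (but not its count of channels), all tests in this part were chosen after the result they bear on had been seen. The control spots, which no comparison uses, gave signal on the second array of each slide, at a median of 1.28 times background over 8 channels against 0.988 times on the first arrays. No explanation for it was tested.

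lp_0514 went against the strain labels on the first array of each slide. Exchanged dyes alone are argued against, since only 4 of 8 channels then matched, and growth phase as labelled too, since both labelled phases (2) held channels with and without the gene. With lp_0514 taken as the deleted gene, correct strain labels throughout are argued against, since only 2 of 8 channels matched. On the stationary array labelled mutant in both dyes the gene was at 12.1 times background in Cy3 and 1.46 times in Cy5. Which labels are wrong is not settled. The unequal arrays may carry both strains in opposite dyes. On both of them 16 other genes lay beyond 1 in opposite directions and 0 in the same direction. These 16 were the capsular run with lp_1196 and the genes close together from lp_0076 on, so they are not independent of each other. A layout with the logarithmic labels on the first arrays of slides 1 to 4 and the dyes exchanged matched 8 of 8 channels. Of 48 assignments of these labels 2 matched, and these 2 name the same strain as each other in every channel, so they are 1 layout. It would leave the stationary labels for the second arrays, which was not tested. The layout was found from these same values, so it is a hypothesis and no group was changed by it. Whether the arrays shared RNA pools stays open, because sums of ratios over a closed loop of 4 pools correlated at 0.19, -0.326 and -0.356 in the 3 pairings, where a shared dye effect adds to each, and because the 0.0687 of the unequal arrays without their 17 opposite genes (-0.599 with them) follows a selection on the outcome.

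Second arrays did not resemble first arrays of the same slide. Growth phase as labelled is argued against, since channels of the same labelled phase across positions correlated lower than channels of the same position across phases, with a difference of -0.49, and a shifted or turned grid too, since no turn or shift of up to 6 rows or columns brought the correlation above 0.0524. Weak signal alone stays open. Only 34.7% of the probes in the brightest decile of a second array were in the brightest decile of the first array on its slide, against 64.7% or more between first arrays. That share fell on the side set in advance against weak signal. But both arrays of each pair of first arrays had strong signal, so the test cannot tell what a weak array of the same RNA would share. Growth phase under wrong phase labels stays open, since the design has 4 arrays of each phase and, of genes with 1 probe in the brightest decile, 47.7% to 54.9% on second arrays had the next probe there too, against 54.2% to 71.2% on first arrays. Any other difference in RNA predicts the same. In this share 7 of 8 channels of second arrays lay below every channel of first arrays, and their probe agreement over all genes was lower (0.398 to 0.508). Whether phase could lower either was not tested.

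The run of capsular genes from lp_1197 on reversed between 2 first arrays. Background correction is argued against, since without it the median size of the ratio was still 3.29 on the array where it was smaller. A second genetic or phase-variable difference between the strains may go with the deletion, and on 4 of 4 first arrays the ratio of lp_0514 and the median of the run lay either both beyond 1 on the log2 scale or both within it, although on the logarithmic array labelled wild type in both dyes, counted as within, all 11 genes of the run lay below 0 (-0.463 to -0.18). A regulatory effect of the deletion predicts the same, so these cannot be told apart with 4 arrays on which they went together at this limit.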

How the results depend on the processing

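Fits on the first or second arrays alone and with codes 2 and 3 left out, and list tests with the slide as a block, were chosen after seeing the data, the rest before. For every change listed, the cause was not tested. Signal near background on second arrays, 1.45 to 1.97 times it, limits all fits that hold them.

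The count of 12 genes in logarithmic phase became 0 with no background correction, plain subtraction, a test per probe, either fit over all 8 arrays, the same-strain arrays left out, the authors' ratios, first arrays alone or second arrays alone. It was 7 with median centring, 22 with scaling between arrays, 4 with code 3 spots kept, 2 with no dye term, 1 of only 178 genes tested with codes 2 and 3 left out, and 0 to 21 with an array left out. It stayed within 1.5 times with dim probes left out, the median of probes and the slide as a block (9, of which 7 were among the 12, without lp_0076 at adjusted p = 0.0727).

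The fitted value of lp_0514 in logarithmic phase kept its direction throughout (main value 3.17, adjusted p = 0.000949) but no longer passed in limma at 2.12 with no background correction (adjusted p = 0.0747), 3.64 with plain subtraction (0.807), 2.42 with code 3 spots kept (0.0643), 2.61 with the authors' ratios (0.981), 3.48 for the only probe with a value on all 4 arrays (0.0575), 6.30 on first arrays (0.108) or 2.11 on second arrays (0.353). At an unchanged 3.17 it did not pass over all 8 arrays with a shared dye term (0.771) or a dye term per phase (0.614), or with the same-strain arrays left out (0.936). With an array left out it lay between 1.92 and 4.43, not passing at 1.92 without the array of mutant in Cy5.

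lp_1198 (-2.68), lp_1197 (-2.56) and lp_1196 (1.97) in logarithmic phase kept their direction but did not pass with no background correction, plain subtraction, either fit over all 8 arrays, the same-strain arrays left out, the authors' ratios, first or second arrays alone, or without the array of mutant in Cy5. In addition lp_1198 and lp_1197 did not pass with code 3 spots kept or no dye term, lp_1198 with the median of probes (-2.30, adjusted p = 0.127), lp_1197 with median centring (-2.48, adjusted p = 0.053), and lp_1196 with dim probes left out (1.385, adjusted p = 0.358) or without the array of mutant in Cy3 (2.58, adjusted p = 0.184). Over all alternatives their adjusted p lay between 1.36e-11 and 0.999.

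The stationary count of 0 became 1 with the slide as a block, the same-strain arrays left out, first arrays alone or second arrays alone, and 0 to 13 with an array left out. The 1 gene was lp_2778, except on first arrays. lp_0514 in stationary phase (-0.28) was at 1.96 on first arrays and -2.33 to 1.77 with an array left out. The count of the difference between phases (0) was 1 with the authors' ratios, the slide as a block or second arrays alone, and 0 to 1 with an array left out. The same-strain count in logarithmic phase (0) was 1 with the strain term fitted. The list count of 1 in logarithmic phase was 0 with an estimated correlation, fry or median centring and 0 to 1 with an array left out. The stationary one (1) was 0 with an estimated correlation and 0 to 2 with an array left out. With the slide as a block both list counts stayed at 1, with the capsular span at adjusted p = 0.0365 in logarithmic and the plantaricin locus at 0.00909 in stationary phase. These fits compare first with second arrays, so a strain effect in them cannot be told apart from position.

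No value that passed in either of the fits compared had opposite signs in them. lp_0514 in stationary phase, which never passed, did change sign. For other single genes, 277 values in logarithmic and 361 in stationary phase kept direction and side of the threshold, 130 and 0 no longer passed, 2 and 11 newly passed, and 10 and 17 that had not passed changed sign. Single genes other than lp_0514 were not run per probe. No analysis paired by replicate number was possible, because these numbers were given in accession order and pair no samples. The slide, which pairs arrays, was fitted as a block.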

Other observations

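All of the following were chosen after the values were seen, and each is given as values only. The reversal between the logarithmic array of mutant against wild type and the stationary array labelled mutant in both dyes was not limited to the capsular run. With all spots kept, 22 genes lay beyond 1 on the first and 21 on the second, and 17 lay beyond 1 on both, all 17 in opposite directions, where independent lists would share 0.15. Besides the 11 capsular genes these were lp_1196, lp_0514 and 4 genes close together starting at lp_0076, whose median was 2.85 on the first array and -3.24 on the second. Neighbouring genes are not independent of each other, so the 0.15 does not measure how rare such an overlap is. The highest number of opposite genes in any other of the 28 pairs of arrays was 11, and among other pairs of first arrays 2. The correlation of both arrays over all 3092 genes was -0.599.

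A run of 10 genes near the start of the capsular span behaved differently from the run described above. On the logarithmic array labelled wild type in both dyes its median log2 Cy5 over Cy3 was -0.64, with all 10 genes between -0.85 and -0.33. On the first stationary array of mutant against wild type it was 0.37, with genes between 0.16 and 0.59. It was 0.20 on the logarithmic array of mutant against wild type and -0.06 on the stationary array labelled mutant in both dyes. On the 4 second arrays its median lay between 0.0651 and 0.384, with genes between -1.11 and 1.46. Ratios of the logarithmic array labelled wild type and the first stationary array of mutant against wild type correlated at -0.341 across 3092 genes. No test between groups was made on this run.

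Genes of fatty acid synthesis had too few measured members to be tested above. With all spots kept, 13 of 13 genes had a ratio above 0 on the logarithmic array labelled wild type in Cy5 and mutant in Cy3, and 13 of 13 below 0 on the stationary array labelled in the same way and on the logarithmic array labelled wild type in both dyes. The median of the 13 genes was 0.78 on the logarithmic and -0.76 on the stationary array labelled wild type in Cy5 and mutant in Cy3, -0.47 on the logarithmic array labelled mutant in both dyes and 0.27 on the stationary array labelled wild type in both. On the 4 first arrays it lay between -0.11 and 0.18. The medians outside this range thus all came from second arrays, where median signal was only 1.45 to 1.97 times background. The 13 genes have consecutive locus tags and are not independent of each other. The 6 teichoic acid genes had medians between -0.36 and 0.06 over the 8 arrays and the 8 ATP synthase genes between -0.33 and 0.08, with no gene of either list beyond 1.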
